A study of Mus musculus with 55 samples.

How the data were processed

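RNA from the cerebellum of mouse pups was measured on Affymetrix Mouse Gene 1.0 ST arrays, which read each transcript with many short probes that are summarised into 1 value per probe set. The 55 arrays fell into 12 groups, formed by 4 genotypes and 3 treatments. The deposited values were taken as log2 expression levels, since they ranged from 1.15 to 14.80 and their notes name no base. Per the submitters' processing notes, they came from Affymetrix Expression Console 1.1 with RMA, a method that corrects background, brings all arrays to a common distribution and summarises probes. No further normalisation was applied, and array medians lay between 7.37 and 7.54.

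The table held 35557 probe sets. Of these, 21789 had 1 gene symbol, 1621 had several and 12147 had none in the probe annotation used here, and only those with 1 symbol were used. The gene identifiers of 21698 probe sets were found in the GRCm38.p6 gene table, and 0 symbols changed through them. No genome build was named by the sources used here, so positions along chromosomes are not printed. The gene table served for names, chromosomes and neighbours. For the 999 genes with several probe sets, the one with the highest mean over all arrays was taken, which gave 19938 genes. Genes above the 25th percentile of the mean level (6.44 on the log2 scale) numbered 14953. Leaving out 3 sex-linked genes gave 14950 genes tested, because sex is not labelled.

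Differences were tested with limma 3.58.1 in R 4.3.3, with figures drawn in Python 3.11.15. All 55 arrays entered 1 fit with a mean for each group and the array date (2 dates) as a covariate. Arrays whose description carries the same number before the point, of which there were 36 such numbers, were treated as correlated. The labels do not say what this number stands for. It was shared by more than 1 array in 17 cases, covering 36 arrays, and the correlation estimated by duplicateCorrelation was 0.131. It was estimated once and kept in every alternative. The moderated tests used a trend of the variance with level and had 42 residual degrees of freedom. P-values were adjusted by Benjamini and Hochberg's method within each of 18 comparisons, and a gene passed at an adjusted p under 0.05. The comparisons were each dose of chlorpyrifos oxon (CPO) against vehicle in each genotype and on the mean of 4 genotypes, 4 pairs of genotypes on the mean of 3 treatments, and the difference of the dose effect between KO and WT and between R192 and Q192. The p-values measure only the spread between these samples, since the labels do not state that each array is a separate animal. For arrays, their number limits the precision.

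Gene lists for cell types, pathways and stress responses were tested with cameraPR of limma on the moderated statistics, two-sided, with a preset inter-gene correlation of 0.01 and, as an alternative, a correlation estimated from the residuals of each list. Of 32 lists, 31 had at least 3 tested genes. On 20 shuffles of the residual columns of the arrays, each read as 14 comparisons, the preset test called a median of 9 lists and at most 20, while the estimated one called a median of 0 and at most 3. Some gene passed in 8 of the 280 shuffled comparisons, with at most 2805 genes. The Pon family between KO and WT was the only list call that held with an estimated correlation, so the others are given as values.

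The groups, comparisons, tests, lists, most alternatives and the rule for naming genes were chosen before the data were examined. The rule named all genes that passed if they were 20 or fewer, and otherwise the 10 largest rises and 10 largest falls. Where fewer than 6 passed, it added the 3 higher and 3 lower genes with the smallest p, given as values that did not pass. This last part did not cover the differences of dose effects. For each list called with the preset correlation it took the 4 members with the smallest p in the direction of the list. These members are named only where they passed over all genes tested. It also took Pon1, Pon2, Pon3, Ache and Bche throughout, and in genotype comparisons those flanking genes of Pon1 that passed.

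The fit was tested on simulated data with 200 of 14950 genes changed, 50 at each size. The simulated genes varied independently of each other, unlike the genes of the real arrays. The figures therefore hold for that setting only, and up to 2805 genes passed on the shuffled real residuals. For CPO at 0.35 in WT, it called 56%, 86%, 100% and 100% of genes changed by 0.3, 0.5, 1 and 2 on the log2 scale, with 7 unchanged genes called. For CPO at 0.5 in KO, it called 24%, 80%, 100% and 100%, with 7 unchanged genes called. For KO against WT, it called 90%, 98%, 100% and 100%, with 11 unchanged genes called. A search for repeated arrays over the 104 pairs within groups found none identical, the smallest root mean square difference being 0.139 on the log2 scale.

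Alternatives changed 1 choice at a time. They left out the date covariate, the number correlation or the level filter, added the replicate number, centred each array on its median, weighted arrays by quality, used 1 date only, added a sex score, tested every probe set, used vehicle arrays only, or left out each array in turn. The sex score had been planned as Xist minus the mean of Ddx3y and Eif2s3y, and was Xist minus Eif2s3y because Ddx3y has no probe set in the annotation used here. Alternatives chosen after seeing the data left out KO 0.35 replicate 5, the 3 arrays with high Xist, or both sets, or added the mean of brainstem markers or the first principal axis of all genes as a covariate.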

Results

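Cerebella of C57Bl/6 mouse pups were profiled at postnatal day 22 after daily injections from day 4 to day 21. The pups received chlorpyrifos oxon (CPO), the active metabolite of the insecticide chlorpyrifos, at 0.35 or 0.5 mg/kg/day, or its vehicle dimethyl sulfoxide. CPO inhibits acetylcholinesterase, and paraoxonase 1 (PON1) is an esterase that hydrolyses it. The genotypes were wild type (WT), Pon1 knockout (KO), and mice carrying a human PON1 transgene with glutamine (Q192) or arginine (R192) at the variable position. In WT there were 6 vehicle arrays, 6 at 0.35 and 3 at 0.5. In KO there were 4, 5 and 3, and in each of Q192 and R192 there were 4, 5 and 5. In the same order these arrays carry 4, 3 and 2 description numbers in WT and 3, 4 and 2 in KO. In Q192 they carry 3, 3 and 3 and in R192 3, 4 and 3. Apart from the number that KO 0.35 replicate 5 shares with R192 0.35 replicates 3 and 4, no number spans groups. Differences between numbers therefore enter the group differences. Each group had arrays of both array dates. The comparisons ask whether CPO changed cerebellar expression, whether the genotypes differed, and whether the CPO response depended on genotype.

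Pon1 was measured first in every array, because it checks the genotype labels, and it went against the label of the knockout. Its log2 level was 10.08 ± 0.19 (SD, n = 12) in arrays labelled KO, 10.10 ± 0.14 (n = 14) in Q192 and 10.13 ± 0.11 (n = 14) in R192, against 5.19 ± 0.24 (n = 15) in WT. The highest WT array had 5.55 and the lowest of the other 40 had 9.78, so the groups did not overlap. The WT level lies under the level filter of 6.44, so the size of the difference is limited by the background of the array and no fold is given. Where the probes lie relative to the disrupted part of the gene is not given in the sources used here, and probes outside it would check nothing. The group is therefore called arrays labelled KO, and every direction drawn from it carries this doubt.

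**Figure D1:**
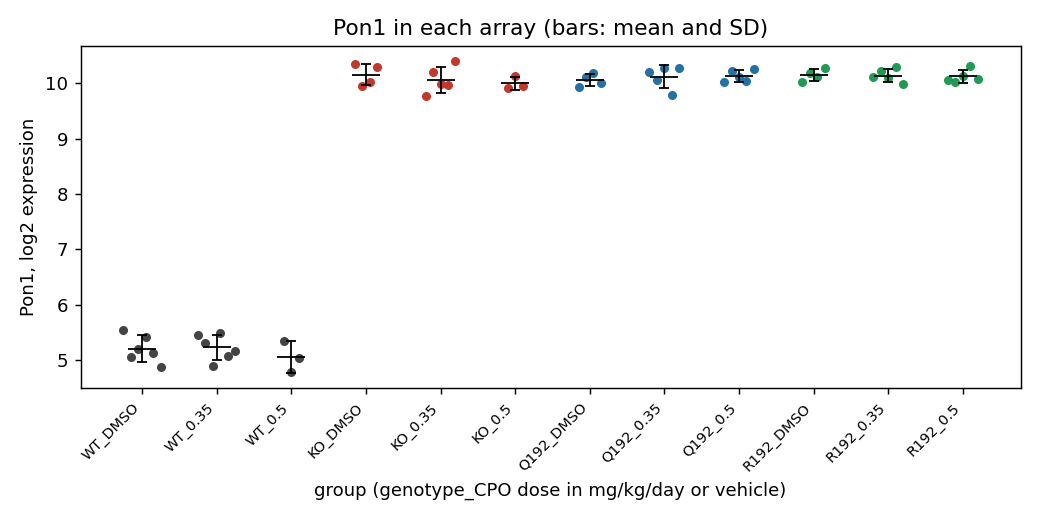
Pon1 level (log2) of each array in the 12 groups of genotype and treatment, with the mean and SD of each group. The 15 WT arrays lie between 4.79 and 5.55 and the 12 arrays labelled KO between 9.78 and 10.39.

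Markers of neighbouring tissue varied between arrays. Mean levels of 30 brainstem and midbrain neuron markers ran from 7.06 in WT 0.35 replicate 2 and 7.13 in replicate 1 to 8.30 in WT vehicle replicate 4. Those of 21 granule neuron markers, the most numerous neurons of the cerebellum, ran from 9.27 in WT vehicle replicate 4 to 11.32 in WT vehicle replicate 1. The brainstem mean was 7.64 ± 0.42 (SD, n = 6) in WT at 0.35, 8.02 ± 0.06 (n = 3) in WT at 0.5 and 8.03 ± 0.28 (n = 6) in WT vehicle. Ribosomal protein genes averaged 11.05 ± 0.04 in WT at 0.5 and 10.80 ± 0.17 in WT vehicle. The first and second principal axes of all genes held 27.5% and 25.8% of the variance.

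**Figure D2:**
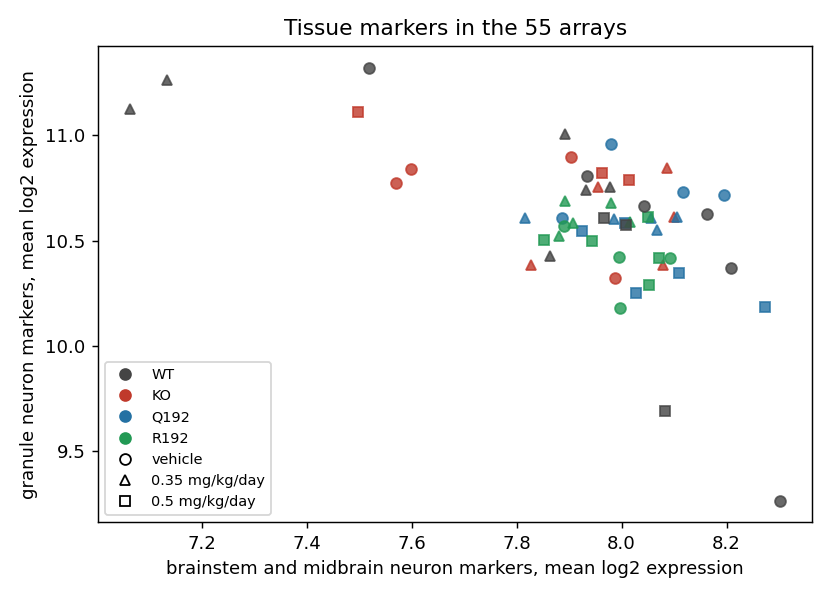
Mean log2 level of brainstem and midbrain neuron markers against that of granule neuron markers for each of the 55 arrays, coloured by genotype, with the symbol giving the treatment. WT 0.35 replicates 1 and 2 lie apart at brainstem levels of 7.13 and 7.06, and WT vehicle replicate 4 at a granule level of 9.27.

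Ache, which encodes the acetylcholinesterase that CPO inhibits, and Bche, which encodes butyrylcholinesterase, passed in none of the 18 comparisons. Ache was 8.47 ± 0.41 (SD, n = 6) in WT at 0.35 against 9.01 ± 0.27 (n = 6) in WT vehicle, a log2 difference of -0.52 (SE 0.181, limma adjusted p = 0.131). In arrays labelled KO it was 8.88 ± 0.40 (n = 5) at 0.35 against 8.48 ± 0.48 (n = 4), a difference of +0.42 (SE 0.204, adjusted p = 0.66). The difference of these effects was +0.94 (SE 0.273, adjusted p = 0.0756).

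In WT at 0.35, 1 gene passed. Mid1, a ubiquitin ligase gene that spans the pseudoautosomal boundary of the mouse X chromosome, rose by 1.11 on the log2 scale (SE 0.186, limma adjusted p = 0.00426). Its level was 10.15 ± 0.59 (SD, n = 6) against 9.04 ± 0.38 in vehicle (n = 6), and all 6 treated arrays were above the vehicle mean. The genes next in rank did not pass (adjusted p = 0.12), among them Tmem267 (+0.78), Bmp5, a bone morphogenetic protein (+0.61), Ptchd4 (+0.43, with +0.36 for its other probe set), Usp11, a deubiquitinase (-0.43), Srpx2 (-0.39) and Fah, the last enzyme of tyrosine breakdown (-0.35). At an unadjusted p under 0.05 there were 3032 genes, where chance gives 748 on average. Genes vary together, so such counts move widely, and R192 at 0.5 had 152. The count of 3032 fell without the 3 arrays of high Xist and with the brainstem markers as a covariate. WT 0.35 replicates 1 and 2 are among those 3 (Xist 11.06 and 11.33), and no WT vehicle array is.

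Lists of oligodendrocyte and microglia genes lay lower in WT at 0.35, with no member passing over all genes tested. Of 24 oligodendrocyte and myelin markers, 24 were lower (median -0.38), and 21 passed adjusted over the list alone (cameraPR adjusted p = 7.65e-12, and adjusted p = 0.263 with an estimated correlation). Of 21 microglia markers, 21 were lower (median -0.26, 10 adjusted over the list alone, adjusted p = 1.25e-07, and adjusted p = 0.263 with an estimated correlation). Cholesterol biosynthesis had a median of -0.36 over 21 genes, with 15 passing adjusted over the list alone (adjusted p = 9.09e-10, and adjusted p = 0.263 with an estimated correlation). The 23 genes of the cholinergic system had a median of -0.18, with 4 lower adjusted over the list alone (adjusted p = 0.0114, and adjusted p = 0.345 with an estimated correlation). Granule neuron markers were higher in 20 of 21 (median +0.37, 3 adjusted over the list alone, adjusted p = 5.42e-07, and adjusted p = 0.406 with an estimated correlation). Brainstem and midbrain neuron markers were lower in 28 of 30 (median -0.32, 9 adjusted over the list alone, adjusted p = 3.64e-05, and adjusted p = 0.345 with an estimated correlation), with WT 0.35 replicates 1 and 2 the lowest of all arrays. The count was 1 on date 1 and 2043 on date 2. It was 1328 without WT 0.35 replicate 4 and 847 without WT vehicle replicate 1, and Mid1 missed the threshold with the sex score (+0.98, adjusted p = 0.0593), without the 3 arrays of high Xist (+0.88, adjusted p = 0.534) and with the brainstem markers as a covariate (+0.96, adjusted p = 0.171).

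In WT at 0.5, 155 genes passed, 37 higher and 118 lower. Calr, which encodes the endoplasmic reticulum chaperone calreticulin, fell by 0.63 on the log2 scale (SE 0.152, adjusted p = 0.0337), and Hyou1, another chaperone gene, by 0.55 (SE 0.127, adjusted p = 0.0323). Lman2l, which encodes a lectin of the secretory pathway, fell by 0.64 (SE 0.115, adjusted p = 0.0147). Gad1, which makes GABA, changed by -0.58 and App, the amyloid precursor gene, by -0.57. The vesicle amino acid transporter gene Slc6a17 changed by -0.59, Sez6l by -0.59 and Mtss1, a regulator of the membrane and actin, by -0.60. Slc38a5, a glutamine transporter gene, changed by -0.59 and Safb by -0.56. The largest rises were Atr, the DNA damage kinase gene (+0.46, SE 0.115, adjusted p = 0.0364), Smim26 (+0.44), Rpl36a (+0.43), Sytl2 (+0.43), Zfp280c (+0.43), the tubulin chaperone gene Tbca (+0.41), Ndufs6 (+0.41) and Ndufa6 (+0.40) of respiratory complex I, Atp11b (+0.39) and the peroxisome gene Pex2 (+0.39). Each of the 28 genes named for this comparison changed in its direction in 3 of 3 treated arrays. The genes were chosen from these same arrays, here and in the like counts for other comparisons, so such counts are no separate support.

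Genes of protein synthesis and respiration lay higher in WT at 0.5. Of 41 ribosomal protein genes, 41 were higher (median +0.25), 2 passed over all genes tested, namely Rps14 (+0.35) and Rpl38 (+0.36), and 27 adjusted over the list alone (adjusted p = 2.27e-18, and adjusted p = 0.406 with an estimated correlation). The mean score on the first principal axis was -8.21 in WT at 0.5 and 9.86 in WT vehicle. Of 71 oxidative phosphorylation genes, 60 were higher (median +0.18), 3 passed over all genes, namely Ndufs6, Ndufa6 and Ndufb5 (+0.36), and 31 higher and 1 lower adjusted over the list alone (adjusted p = 1.6e-14, and adjusted p = 0.406 with an estimated correlation). Heat shock and unfolded protein response genes had a median of -0.24 over 30, with Calr, Hyou1 and Hsph1 (-0.47) passing over all genes, and 13 lower and 1 higher adjusted over the list alone (adjusted p = 0.000152, and adjusted p = 0.431 with an estimated correlation). The synaptic vesicle cycle had a median of -0.18 over 33, with Unc13a (-0.47), which primes vesicles, and Nsf (-0.45), which drives fusion, passing over all genes, and 12 lower and 1 higher adjusted over the list alone (adjusted p = 0.000567, and adjusted p = 0.431 with an estimated correlation). The other 2 probe sets of Unc13a had -0.40 and -0.15. The adhesion gene Ncam1 (-0.54) was the 1 axon guidance gene of 57 that passed over all genes, where 9 lower passed adjusted over the list alone (adjusted p = 0.000771, and adjusted p = 0.431 with an estimated correlation). Ndufa4 (+0.27), which lies near Pon1, also passed.

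The count in WT at 0.5 depended on single arrays. It was 211 without the date covariate, with 153 of the 155 among them. It was 0 by limma on date 1 alone and 0 on date 2 alone, which leave 1 and 2 treated arrays, with 975 and 3018 genes at an unadjusted p under 0.05. Without WT 0.5 replicate 1, 2 or 3 it was 27, 0 (2039 at an unadjusted p under 0.05) and 4, and without WT vehicle replicates 1 to 6 it was 26, 4, 378, 834, 1 and 2, so none of the 28 named genes passed without each array in turn. With each array centred on its median, 56 genes passed, 7 higher and 49 lower, and 72 passed with the replicate number in the fit. With the first principal axis as a covariate 8 passed, of which 3 were among the 155. Other alternatives raised the count and kept all 155, with 2515 genes (991 higher and 1524 lower) with array quality weights, 720 without the number correlation, 587 with the brainstem markers as a covariate, 489 without KO 0.35 replicate 5, 311 without the 3 arrays of high Xist and 825 without all 4.

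In arrays labelled KO, no gene passed at either dose. At 0.35 the genes with the smallest p did not pass (limma adjusted p = 0.66), among them Syn3, a synapsin gene (+0.35, SE 0.089), Sh2d6 (+0.31), Olfr545 (+0.29), the autophagy gene Gabarapl2 (-0.37, with -0.22 for its other probe set), Ammecr1 (-0.26) and the chaperonin gene Cct8 (-0.22). At 0.5 (adjusted p = 0.387) they were Rdh1 (+0.39, SE 0.110), Foxi3 (+0.36), Chrnb4, a nicotinic receptor subunit gene (+0.33), Gm1976 (-0.83, SE 0.253), Herc4 (-0.28) and Mis12 (-0.26). Limma gave 0 genes at both doses, with 963 genes at 0.35 and 1913 at 0.5 at an unadjusted p under 0.05. Of 71 oxidative phosphorylation genes, 62 were lower at 0.35 (median -0.11), with 0 passing over all genes tested and 0 adjusted over the list alone (adjusted p = 4.38e-14, and adjusted p = 0.709 with an estimated correlation). The mean score on the first principal axis was 4.06 at 0.35 and -5.77 in vehicle, where KO vehicle replicate 1 lay at -28.9. KO 0.35 replicate 5 lay with the R192 and Q192 arrays in the genes that part arrays labelled KO from R192. On date 1 and date 2 alone the counts were 0 and 0 at 0.35 (970 and 363 at an unadjusted p under 0.05) and 0 and 0 at 0.5 (525 and 904). The count at an unadjusted p under 0.05 moved with single arrays. At 0.35 it was 571, 1492, 572 and 2941 without KO 0.35 replicates 1, 2, 4 and 5, and 244 and 2139 without KO vehicle replicates 1 and 2. At 0.5 it was 557 without KO 0.5 replicate 3, and 326, 3358 and 1143 without KO vehicle replicates 1, 2 and 4.

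In Q192, no gene passed at either dose. At 0.5 immediate early genes, which neurons switch on with activity, held the largest differences among the genes with the smallest p. Nr4a1 was 7.81 against 8.90 in vehicle, a log2 difference of -1.07 (SE 0.254, limma adjusted p = 0.332, lower in 5 of 5 arrays), and Dusp1 was 9.27 against 10.21, a difference of -0.93 (SE 0.228, adjusted p = 0.332, lower in 5 of 5 arrays). Of 29 such genes, 27 were lower (median -0.21), 0 passed over all genes tested and 10 adjusted over the list alone (adjusted p = 7.02e-10, and adjusted p = 0.273 with an estimated correlation). All 41 ribosomal protein genes were higher at 0.5 (median +0.20), with 0 passing over all genes and 22 adjusted over the list alone (adjusted p = 1.54e-17, and adjusted p = 0.289 with an estimated correlation). The mean score on the first principal axis was -5.41 in Q192 at 0.5 and 8.39 in Q192 vehicle, and granule neuron markers averaged 10.38 ± 0.18 (SD, n = 5) and 10.75 ± 0.15 (n = 4). The other values at 0.5 were Tmod1 (-0.41, adjusted p = 0.213, with -0.04 for its other probe set), Slx4ip (+0.33), Wdr47 (+0.21) and Clns1a (+0.20). At 0.35 (adjusted p = 0.999) they were Ang5 (+0.38), Ccdc190 (+0.29), Prtg (+0.28), Dcp1a (-0.22), Ppp2r5e (-0.18) and Rab6a (-0.17). Limma gave 0 genes at both doses, with 306 genes at 0.35 and 1974 at 0.5 at an unadjusted p under 0.05. On date 1 and date 2 alone the counts were 0 and 0 at 0.35 (177 and 139 at an unadjusted p under 0.05) and 0 and 0 at 0.5 (811 and 483), and with array quality weights 629 genes passed at 0.5. The count at an unadjusted p under 0.05 was 540 at 0.35 without Q192 0.35 replicate 4, 488 and 152 without Q192 vehicle replicates 3 and 4. At 0.5 it was 1137 and 1037 without Q192 vehicle replicates 1 and 4.

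In R192, no gene passed at either dose. Dhrs3, a retinaldehyde reductase gene, was among the values with the smallest p at both, with +0.35 (SE 0.094, limma adjusted p = 0.921) at 0.35 and +0.28 (SE 0.095, adjusted p = 1) at 0.5, and higher in 5 of 5 arrays each time. The other values at 0.35 were the myosin gene Myo10 (+0.30), Klhl22 (+0.21), Fndc11 (-0.29), Mogat2 (-0.26) and Kctd14 (-0.23). At 0.5 they were Amacr (+0.22), Rgs20 (+0.20), the replication licensing gene Cdc6 (-0.31), Gapdhs (-0.23) and Baiap2l1 (-0.15, with -0.11 and -0.09 for its other probe sets). Granule neuron markers were higher in 21 of 21 at 0.35 (median +0.27), with 0 passing over all genes and 0 adjusted over the list alone (adjusted p = 0.000328, and adjusted p = 0.663 with an estimated correlation). Limma gave 0 genes at both doses, with 536 genes at 0.35 and 152 at 0.5 at an unadjusted p under 0.05, and 0 on either date alone (156 and 264 at 0.35, 165 and 160 at 0.5). The count at an unadjusted p under 0.05 was 999, 333 and 280 at 0.35 without R192 0.35 replicates 2, 3 and 5, 198 and 862 without R192 vehicle replicates 2 and 3. At 0.5 it was 96 without R192 0.5 replicate 5.

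On the mean of the 4 genotypes, no gene passed at either dose. At 0.35 the values with the smallest p were Hp, which encodes haptoglobin (+0.18), Six5 (+0.15), the interferon signalling gene Irf9 (+0.13), the aldehyde dehydrogenase gene Aldh1a7 (-0.25), Piga (-0.20) and Gm340 (-0.13), all at a limma adjusted p of 1. At 0.5 they were Gm5464 (+0.16), Slc22a20 (+0.16), 6530409C15Rik (+0.13), Tox4 (-0.18), Zbtb8b (-0.13) and Txlna (-0.10), at an adjusted p of 0.991. Myelin markers were lower in 24 of 24 at 0.35 (median -0.13), with 0 passing over all genes and 0 adjusted over the list alone (adjusted p = 8.31e-14, and adjusted p = 0.559 with an estimated correlation). WT at 0.35, where all 24 were lower too, is part of this mean. That group holds WT 0.35 replicates 1 and 2, the lowest of all arrays in brainstem markers (7.13 and 7.06). Limma gave 0 genes at both doses, with 274 genes at 0.35 and 724 at 0.5 at an unadjusted p under 0.05. On date 1 and date 2 alone it gave 0 and 0 at 0.35 (283 and 576) and 0 and 0 at 0.5 (438 and 458), and 226 genes passed at 0.5 with array quality weights. The count at an unadjusted p under 0.05 was 415 at 0.35 without KO 0.35 replicate 5 or WT 0.35 replicate 4, 437 without Q192 vehicle replicate 1 and 524 without WT vehicle replicate 1. At 0.5 it was 1245 without KO vehicle replicate 1.

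Between arrays labelled KO and WT, 56 genes passed, 26 higher and 30 lower in those labelled KO. Pon1 was higher in 12 of 12 (limma adjusted p = 2.06e-43), and no size is given since WT lies under the level filter of 6.44. The largest other difference was in Gdpd3, a lysophospholipase D gene, at 6.24 ± 0.16 (SD, n = 12) against 8.52 ± 0.28 (n = 15), a log2 difference of -2.28 (SE 0.083, adjusted p = 5.51e-27, lower in 12 of 12), a size that background limits as well, since the level in arrays labelled KO lies under the filter. Pglyrp1, which encodes a peptidoglycan recognition protein of innate immunity, was 8.63 ± 0.23 against 7.64 ± 0.12, a difference of +0.98 (SE 0.074, adjusted p = 8.55e-14, higher in 12 of 12). Higher genes also included Psg16 (+0.69), Coch (+0.63), the pyruvate dehydrogenase kinase gene Pdk4 (+0.54), Rabl2 (+0.48), Zfp109 (+0.48), Tmc7 (+0.44), the talin gene Tln2 (+0.35) and Gm8995 (+0.34). Lower genes included Gm1976 (-1.30), Plekhd1 (-1.06), Snapc1, a subunit of the complex that activates small nuclear RNA genes (-0.66), Slc38a6 (-0.58), Cplane2 (-0.57), Olfml1 (-0.53), Gm7276 (-0.45) and Snora16a (-0.42). Q192 and R192 lay with arrays labelled KO and apart from WT in Pon1, in Gdpd3 (6.30 and 6.25) and in Pglyrp1 (8.65 and 8.49). Other genes went the other way, among them Gm1976, Plekhd1, Snapc1 and Slc38a6, which were higher in Q192 and R192 than in arrays labelled KO. Because Pon1 goes against the label, which of these groups lacks PON1 is not settled by these values.

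Of the 56 genes, 54 were placed on a chromosome. Chromosome 6, which carries Pon1, held 10 of them (739 genes tested there). More lay on chromosome 7, with 23 (1193 tested), and 8 lay on chromosome 12 (551 tested). No other chromosome held more than 5. Whether the genes away from chromosome 6 differ because of the knockout was not tested. The genes that flank Pon1 included 5 of the 56. Pon2, the adjacent paralogue, was 9.53 ± 0.15 (SD, n = 12) in arrays labelled KO against 9.86 ± 0.20 (n = 15), a difference of -0.37 (SE 0.056, adjusted p = 2.37e-05, lower in 12 of 12 arrays). Ica1 (-0.49), Mios (-0.39), Pdk4 and the glucocorticoid-induced gene Glcci1 (+0.29) were the others, and Pon3 was -0.30 (SE 0.092, adjusted p = 0.257). Of the 31 flanking genes tested, 2 higher and 3 lower passed over all genes and 2 higher and 5 lower adjusted over the list alone (adjusted p = 0.0126, and adjusted p = 0.479 with an estimated correlation). The Pon family list rested on Pon1 alone, with a median of -0.30 and a test in the upward direction (adjusted p = 2.19e-146, and adjusted p = 1.65e-95 with an estimated correlation). Its counts were 1 higher and 1 lower over all genes, and 1 higher and 2 lower adjusted over the list alone. Microglia markers were lower in 20 of 21 (median -0.15), with 0 passing over all genes and 7 adjusted over the list alone (adjusted p = 8.58e-09, and adjusted p = 0.276 with an estimated correlation).

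Of the 23 genes named between arrays labelled KO and WT, 16 had every array labelled KO on the same side of the WT mean, and the fewest was 10 of 12, for Tln2. Leaving out each array in turn kept 22 of the 23, and Tln2 missed the threshold without KO 0.5 replicate 3 (adjusted p = 0.105). On date 1 alone 12 genes passed and on date 2 alone 23, of which 12 and 18 were among the 56. With vehicle arrays alone 22 genes passed, and with array quality weights 344.

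Between Q192 and arrays labelled KO, 60 genes passed, 47 higher and 13 lower in Q192. The largest rise in level was in the X-linked G530011O06Rik (+1.78, SE 0.179, limma adjusted p = 1.09e-09, higher in 14 of 14 arrays), followed by Gm1976 (+1.16), Plekhd1 (+0.98), the small nucleolar RNA Snord53 (+0.83), Snapc1 (+0.66), the nucleotidase gene Entpd4 (+0.63), the heat shock family gene Hspa4l (+0.52), Tmem267 (+0.51), Slc38a6 (+0.49) and Cplane2 (+0.48). The lower genes were led by Mrpl20, a mitochondrial ribosomal protein gene, at 8.29 ± 0.20 (SD, n = 14) against 9.33 ± 0.46 (n = 12), a difference of -1.08 (SE 0.102, adjusted p = 3.55e-10, lower in 14 of 14 arrays). Gabra2, the alpha 2 subunit gene of the GABA receptor, was 8.66 ± 0.23 against 9.65 ± 0.17, a difference of -0.99 (SE 0.085, adjusted p = 2.58e-11, lower in 14 of 14). Mid1 (-0.93), AI506816 (-0.93), Wdfy1 (-0.62), the ubiquitin ligase gene Marchf1 (-0.61), Nnt, the mitochondrial transhydrogenase gene (-0.52), Coch (-0.50), Tln2 (-0.33) and Mxra8 (-0.31) were also lower. Pon1 itself differed by +0.03 (SE 0.077, adjusted p = 0.931).

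Among the lists between Q192 and arrays labelled KO, microglia markers were higher in 21 of 21 (median +0.14), with P2ry13 (+0.35) passing over all genes and 5 adjusted over the list alone (adjusted p = 1.89e-09, and adjusted p = 0.489 with an estimated correlation). Ribosomal protein genes had a median of +0.11, with 0 passing over all genes and 20 higher and 1 lower adjusted over the list alone (adjusted p = 1.17e-12, and adjusted p = 0.489 with an estimated correlation). Ndufs6 (+0.27) was the 1 oxidative phosphorylation gene and Pou4f1 (+0.34) the 1 brainstem marker that passed over all genes, and each was also the 1 gene adjusted over the list alone (adjusted p = 0.538 and adjusted p = 0.576 with an estimated correlation). Of the 23 named genes, 20 were in their direction in all 14 Q192 arrays, the fewest being 13, and 16 passed without each array in turn. Tln2 (adjusted p = 0.139), Coch (adjusted p = 0.105), Ndufs6 (adjusted p = 0.0626) and Mxra8 (adjusted p = 0.0567) were weakest without KO 0.5 replicate 3, P2ry13 (adjusted p = 0.135) and Pou4f1 (adjusted p = 0.101) without KO 0.5 replicate 2, and Tmem267 (adjusted p = 0.108) without KO vehicle replicate 1. The counts were 13 on date 1 and 20 on date 2, of which 13 and 19 were among the 60, and 15 with vehicle arrays alone and 1495 with array quality weights.

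Between R192 and arrays labelled KO, 839 genes passed, 397 higher and 442 lower in R192. The largest were Gm1976 (+1.20, SE 0.131, limma adjusted p = 1.52e-08, higher in 14 of 14 arrays) and Mrpl20 at 8.21 ± 0.12 (SD, n = 14) against 9.33 ± 0.46 (n = 12), a difference of -1.12 (SE 0.101, adjusted p = 1.28e-10, lower in 14 of 14). Higher genes also included G530011O06Rik (+1.04), Snord53 (+0.96), Plekhd1 (+0.86), Snapc1 (+0.69), Slc38a6 (+0.61), the protease inhibitor gene Serpinb1a (+0.58), the microglial receptor gene Fcrls (+0.54), Hspa4l (+0.53) and Nlrp5-ps (+0.52). Lower genes included Mid1 (-0.85), Gabra2 (-0.61), Coch (-0.55), the Purkinje cell glutamate transporter gene Slc1a6 (-0.50), the tubulin gene Tubb4a (-0.49), Sez6l2 (-0.48), Dner, a Notch ligand gene of Purkinje cells (-0.48), Rasgrp1 (-0.47) and Trim62 (-0.46). Flanking genes of Pon1 that passed were Gng11 (+0.34), Rpa3 (+0.22, with +0.11 for its other probe set), Sem1 (+0.19), Ndufa4 (+0.15) and Dync1i1 (-0.15), and 5 higher and 3 lower passed adjusted over the list alone (adjusted p = 0.0316, and adjusted p = 0.42 with an estimated correlation).

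Ribosomal protein genes were higher in R192 than in arrays labelled KO in 40 of 41 (median +0.16), with 21 passing over all genes, among them Rpl5 (+0.26), Rps3 (+0.26), Rpl6 (+0.25) and Rplp1 (+0.25), and 31 adjusted over the list alone (adjusted p = 3.48e-22, and adjusted p = 0.25 with an estimated correlation). The mean score on the first principal axis at 0.35, at 0.5 and in vehicle was -2.74, -5.96 and -9.01 in R192 and 4.06, 10.7 and -5.77 in arrays labelled KO. Of 71 oxidative phosphorylation genes, 13 passed over all genes, among them Uqcrh (+0.22) and Sdhb (+0.21), and 26 higher and 1 lower adjusted over the list alone (adjusted p = 8.86e-09, and adjusted p = 0.306 with an estimated correlation). Microglia markers had 7 of 21 higher over all genes, among them the purinergic receptor genes P2ry13 (+0.42) and P2ry12 (+0.30) and Aif1 (+0.20), and 9 adjusted over the list alone (adjusted p = 6.71e-08, and adjusted p = 0.279 with an estimated correlation). Synaptic vesicle genes had 8 of 33 lower over all genes, among them the calcium sensor gene Syt1 (-0.28), Syn2 (-0.29), Unc13a (-0.24, with -0.22 and -0.05 for its other probe sets) and Synj1 (-0.16), and 16 lower and 1 higher adjusted over the list alone (adjusted p = 5.09e-06, and adjusted p = 0.268 with an estimated correlation). Purkinje cell markers had 4 of 20 lower over all genes, among them Gad1 (-0.33), and 4 adjusted over the list alone (adjusted p = 1.94e-06, and adjusted p = 0.306 with an estimated correlation). Axon guidance genes had 3 lower and 1 higher over all genes, among them L1cam (-0.32) and Ncam1 (-0.28), and 10 lower and 1 higher adjusted over the list alone (adjusted p = 0.000354, and adjusted p = 0.306 with an estimated correlation).

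The count between R192 and arrays labelled KO was 10 on date 1 and 121 on date 2, of which 10 and 77 were among the 839, and 4 with vehicle arrays alone. It was 365 without KO 0.5 replicate 3, 455 without R192 vehicle replicate 2, 521 without KO vehicle replicate 3, 1628 without KO vehicle replicate 1 and 2314 without KO 0.35 replicate 5. With each array centred on its median the split was 215 higher and 575 lower. With the first principal axis as a covariate 823 genes passed, 449 higher and 374 lower, of which 464 were among the 839. With array quality weights 5401 passed, 2531 higher and 2870 lower, and without the number correlation 1393, with all 839 among them each time. Of the 53 named genes, 42 were in their direction in all 14 R192 arrays, the fewest being 12, and 31 passed without each array in turn. Without KO 0.5 replicate 3, Rpa3 (adjusted p = 0.188), Sem1 (adjusted p = 0.152), Trim62 (adjusted p = 0.106), Sez6l2 (adjusted p = 0.1), Rasgrp1 (adjusted p = 0.0876), Gng11 (adjusted p = 0.0873), Slc1a6 (adjusted p = 0.0676), Tubb4a (adjusted p = 0.0662), Ndufa4 (adjusted p = 0.0585) and Syn2 (adjusted p = 0.0508) missed the threshold, and Dync1i1 did so without R192 vehicle replicate 1 (adjusted p = 0.063). KO 0.35 replicate 5 lay at 1.16 on a scale of 20 genes where the mean of the other arrays labelled KO is 0 and that of R192 is 1.

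**Figure D3:**
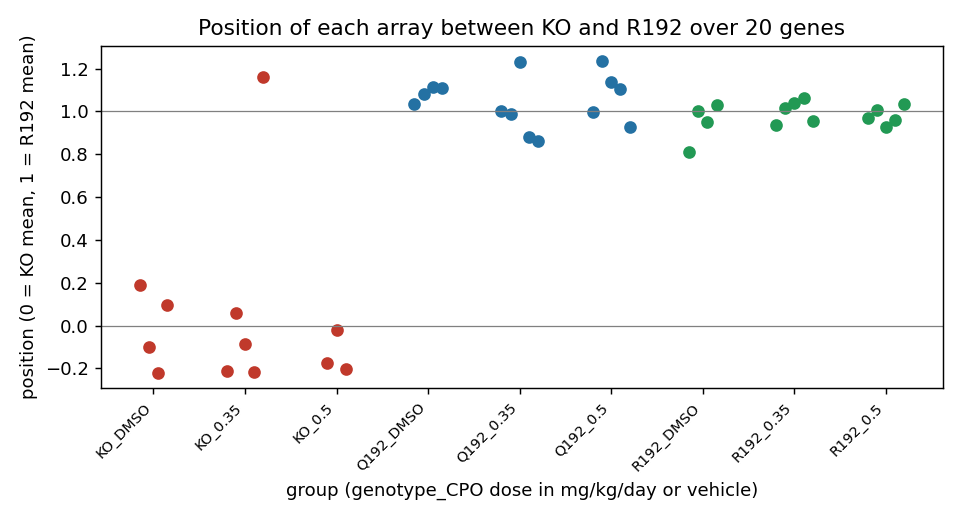
Position of each array labelled KO, Q192 or R192 over 20 genes that part arrays labelled KO from R192. On this scale 0 is the mean of arrays labelled KO and 1 is the R192 mean. Genes and means were drawn anew without each array placed, so KO 0.35 replicate 5 enters them for all other arrays. KO 0.35 replicate 5 lies at 1.16, while the 11 others lie between -0.22 and 0.19, the 14 R192 arrays between 0.81 and 1.06 and the 14 Q192 arrays between 0.86 and 1.23.

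Between R192 and Q192, the carriers of the human alleles, 11 genes passed, 8 higher and 3 lower in R192. Wdfy1, an endosomal adaptor gene, was 8.78 ± 0.07 (SD, n = 14) in R192 against 8.18 ± 0.27 (n = 14), a difference of +0.60 (SE 0.057, limma adjusted p = 7.26e-10, higher in 14 of 14 arrays), and WT had 8.80 ± 0.13 (n = 15). Cd59a, an inhibitor of complement, was 9.61 ± 0.23 against 8.83 ± 0.24, a difference of +0.79 (SE 0.118, adjusted p = 9.7e-05, higher in 14 of 14). Marchf1 (+0.69), AI506816 (+0.63), Gabra2 (+0.38), Spock3 (+0.27), Cnbd2 (+0.24) and Kcnmb1, a potassium channel subunit gene (+0.22), were also higher, and Entpd4 (-0.36), Zkscan3 (-0.29) and Tfg (-0.17) were lower. Immediate early genes were lower in 28 of 29 (median -0.11), with 0 passing over all genes and 0 adjusted over the list alone (adjusted p = 4.98e-06, and adjusted p = 0.423 with an estimated correlation). Pon1 differed by +0.02 (SE 0.073, adjusted p = 0.929).

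Of the 11 genes, 7 were in their direction in all 14 R192 arrays, the fewest being 12, and Cd59a, Cnbd2, Marchf1 and Wdfy1 passed without each array in turn. AI506816 (adjusted p = 0.0696), Kcnmb1 (adjusted p = 0.0983) and Zkscan3 (adjusted p = 0.0623) were weakest without Q192 vehicle replicate 3, Entpd4 (adjusted p = 0.181) and Spock3 (adjusted p = 0.0791) without replicate 4, Tfg (adjusted p = 0.125) without replicate 1 and Gabra2 (adjusted p = 0.177) without R192 vehicle replicate 1. The count was 6 without R192 vehicle replicate 2. It was 7 without Q192 0.35 replicate 2, Q192 0.5 replicate 2 or 4, Q192 vehicle replicate 1 or 4, R192 0.35 replicate 2 or 4, R192 0.5 replicate 1 or R192 vehicle replicate 4. It was 1 on each date alone, 4 with vehicle arrays alone and 291 with array quality weights, and centring gave 5 higher and 1 lower.

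The dose effects were then compared between genotypes. At 0.35, Mid1 was the 1 gene whose CPO effect differed between arrays labelled KO and WT, by -1.49 on the log2 scale (SE 0.279, limma adjusted p = 0.0386). It was 8.83 ± 0.45 (SD, n = 5) at 0.35 and 9.20 ± 0.08 (n = 4) in vehicle in arrays labelled KO, against 10.15 ± 0.59 (n = 6) and 9.04 ± 0.38 (n = 6) in WT. The count was 1 on date 1 and 922 on date 2, where Mid1 was not among them (-1.33, adjusted p = 0.0882). It was 2480 without KO 0.35 replicate 5, 8 without KO 0.35 replicate 2, 1406 without KO vehicle replicate 2, 2 without KO vehicle replicate 3, 2 without WT 0.35 replicate 3, 1523 without WT 0.35 replicate 4 and 757 without WT vehicle replicate 1. It was 0 by limma without KO 0.35 replicate 1 or 4, KO vehicle replicate 1 or 4, WT 0.35 replicate 1, 2 or 6, or WT vehicle replicate 2, 3, 4 or 6, with 1798 to 3960 genes at an unadjusted p under 0.05. With the replicate number in the fit the difference in Mid1 was -1.46 (adjusted p = 0.0527), with centring -1.45 (adjusted p = 0.0722). It was -1.26 with the sex score (adjusted p = 0.324), -1.24 without the 3 arrays of high Xist (adjusted p = 0.362) and -1.25 with the brainstem markers as a covariate (adjusted p = 0.999). With array quality weights it was -1.47 (adjusted p = 0.000879).

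At 0.5, the CPO effect differed between arrays labelled KO and WT in 1375 genes, with 841 higher and 534 lower in those labelled KO. Sez6l2 was 10.28 ± 0.17 (SD, n = 3) at 0.5 and 9.69 ± 0.67 (n = 4) in vehicle in arrays labelled KO, against 9.41 ± 0.34 (n = 3) and 10.26 ± 0.23 (n = 6) in WT, a difference of effects of +1.46 (SE 0.374, limma adjusted p = 0.037). The synaptic gene Clstn3 (+1.23), the synapsin gene Syn1 (+1.23), Ncdn (+1.19), the junction gene Jup (+1.18), Pnmal2 (+1.14), the neuronal chloride transporter gene Slc12a5 (+1.14), Dner (+1.13), Clip3 (+1.13) and the fatty acid synthase gene Fasn (+1.12) followed. The largest negative differences were Zfp442 (-1.15), Gm1976 (-1.14), Mir384 (-1.10), Mir99ahg (-1.06, with -0.54, -0.58 and -0.83 for its other probe sets), Zfp874b (-1.06), Snord61 (-1.02), Gm4787 (-1.001), Mir325 (-0.996), DQ267101 (-0.99) and Etnppl (-0.94).

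No gene among these 20 passed without each array in turn. The count at 0.5 was 0 by limma on date 1 alone and 0 on date 2 alone, with 1163 and 3504 genes at an unadjusted p under 0.05. It was also 0 without KO 0.5 replicate 1 or 3, KO vehicle replicate 1 or 4, WT 0.5 replicate 2 or 3, or WT vehicle replicate 1 or 5, with 2820 to 4384 genes at an unadjusted p under 0.05. It was 2979 without KO vehicle replicate 2, 2169 without KO vehicle replicate 3, and 788 and 854 without WT vehicle replicates 2 and 6. With each array centred on its median the split was 724 higher and 263 lower, and with the first principal axis as a covariate 0 passed by limma, with 620 at an unadjusted p under 0.05. Without the 3 arrays of high Xist the count was 0 by limma, and without the level filter it was 377. It was 1482 without KO 0.35 replicate 5 and these 3, 2075 without KO 0.35 replicate 5 alone and 2139 with the brainstem markers as a covariate.

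Between R192 and Q192, limma gave 0 genes whose CPO effect differed at 0.35 and 0 at 0.5, with 831 and 1036 genes at an unadjusted p under 0.05. For Ache, the difference of the effects was +0.38 (SE 0.290, adjusted p = 0.793) at 0.35 and +0.26 (SE 0.292, adjusted p = 0.79) at 0.5. On either date alone limma gave 0 genes at both doses, with at most 286 genes at 0.35 and 481 at 0.5 at an unadjusted p under 0.05, and 2 genes passed at 0.5 with array quality weights. The count at an unadjusted p under 0.05 was 1427 at 0.35 without Q192 0.35 replicate 4, 515 without R192 0.35 replicate 5, 469 without Q192 vehicle replicate 4 and 403 without R192 vehicle replicate 2. At 0.5 it was 594 and 534 without these vehicle arrays.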

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

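The tests of the 3 patterns weighed here were chosen only after the results were seen, while the search for arrays apart from their group and the tests of differing dose effects were planned. Among 120 tests of 12 measures in groups of 4 to 10 arrays, 9 values, from 7 arrays, stood apart from their group, where chance gives about 1 in 20.

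Ribosomal protein genes averaged 11.09 in WT 0.35 replicate 5 (the other 5 arrays 10.68 to 10.82), 11.12 in Q192 0.5 replicate 5 (the others 11.01 to 11.02) and 10.98 in R192 vehicle replicate 3 (the others 11.07 to 11.08). Pon2 was 9.93 in WT 0.35 replicate 5 (the others 9.66 to 9.74) and 9.82 in Q192 0.5 replicate 1 (the others 9.62 to 9.68). Granule neuron markers averaged 10.55 in Q192 0.35 replicate 1 (the others 10.60 to 10.62). Choroid plexus markers averaged 8.12 in R192 0.35 replicate 1 (the others 7.86 to 7.93). In KO vehicle replicate 4, Xist, the RNA of the inactive X chromosome, was 11.26 (the others 5.52 to 5.82) and the Y-linked Eif2s3y was 4.15 (the others 10.39 to 10.97).

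The CPO effect differed between arrays labelled KO and WT by the test of the difference itself, in 1 gene at 0.35, Mid1, and in 1375 genes at 0.5. At 0.5 the count fell to 0 by limma without any of 8 single arrays (KO 0.5 replicate 1 or 3, KO vehicle replicate 1 or 4, WT 0.5 replicate 2 or 3, WT vehicle replicate 1 or 5), with 2820 to 4384 genes at an unadjusted p under 0.05.

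Pon1 was higher in arrays labelled KO than in WT, against the label. The human transgene as what the probes read is argued against, since Q192 differed from arrays labelled KO by 0.03 on the log2 scale. The higher of Pon2 and Pon3 was at -0.30. This does not decide on a transcript of the disrupted allele that runs on past its end. The direction of transcription was not examined, so these 2 genes may not lie in its path. A swap of a few labels is argued against, since 0 of the 40 other arrays lay at or under the highest WT array. A disruption that leaves the probed part of Pon1 in a stable transcript stays open, and no biological explanation was tested.

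KO 0.35 replicate 5 lay apart from the 11 other arrays labelled KO, at 1.16, where these spanned -0.22 to 0.19, R192 0.81 to 1.06 and Q192 0.86 to 1.23. Each array was placed by genes and means drawn without it, so replicate 5 entered those used for all other arrays. A shift along the first principal axis is argued against by KO vehicle replicate 1, which lay farther out on that axis and had a position of 0.189. An effect of CPO is argued against by the other 4 arrays of its group, whose highest position was 0.058. Between Q192 and R192 on a second scale it lay at 1.20, where R192 spanned 0.58 to 1.16 and Q192 -0.10 to 0.34, and it shares its description number with R192 0.35 replicates 3 and 4. Its positions lie just outside the R192 range on both scales, on the side away from the other arrays labelled KO and from Q192. They therefore do not speak against a mislabelled sample. That explanation stays open, as does an unusual array, since no test run here separates them.

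The genes that passed in WT at 0.5 depended on single arrays. Whether brainstem tissue in some dissections was the cause is not decided. A count over a threshold with 3 treated arrays can move with single arrays whatever the cause. With the brainstem markers as a covariate 587 genes passed, and the count still moved with single arrays. It was 278, 1 (0.170% of the 587) and 65 without WT 0.5 replicates 1 to 3, and 62, 85, 1231, 1440, 213 and 375 without WT vehicle replicates 1 to 6. Sex is argued against by the 9 arrays compared, in which Eif2s3y lay above Xist by at least 4.11 on the log2 scale. A shift in RNA or array quality along the first principal axis stays open. Of the 155 genes, 143 (92.3%) changed in the direction of the first axis drawn from the 40 arrays of the other genotypes. The sign of that axis was set by the fold changes of the genes that did not pass in this same comparison (correlation 0.685). A high share was therefore likely from the start and is no separate support. With the first axis of all 55 arrays as a covariate 8 genes passed, 3 of them among the 155. An effect of CPO that runs along the same axis stays open too, as it was not tested.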

How the results depend on the processing

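The tests without KO 0.35 replicate 5, without the 3 arrays of high Xist, or with the brainstem or first-axis covariate were chosen only after the results were seen. For the counts below the cause was not tested, except that 1 date or vehicle alone leaves fewer arrays. On date 1 the WT group at 0.5, and on date 2 the group labelled KO at 0.5, had 1 array, which was assumed to vary like the other groups. Main counts were 1 and 155 in WT at 0.35 and 0.5, 56 for arrays labelled KO against WT, 60 for Q192 and 839 for R192 against arrays labelled KO, 11 for R192 against Q192, and 1 and 1375 for the difference of the CPO effect between arrays labelled KO and WT at 0.35 and 0.5. The other 10 comparisons had 0 by limma, also without each array in turn, and passed 0 under each alternative apart from array weights.

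Without the date covariate, R192 against Q192 gave 7. Without the number correlation there were 372 and 720 in WT, 1393 for R192 against arrays labelled KO, and 506 for the difference at 0.35. Without the level filter there were 101 in WT at 0.5, 7 for R192 against Q192 and 377 for the difference at 0.5. Centring gave 56 in WT at 0.5, 6 for R192 against Q192, and 0 for the difference at 0.35 (3826 at an unadjusted p under 0.05). Array weights gave 2515 in WT at 0.5, 629 in Q192 at 0.5, 226 on the mean of genotypes at 0.5, 344, 1495, 5401 and 291 for the genotype pairs, and 2 for R192 minus Q192 at 0.5. Date 1 alone gave 0 in WT at 0.5 (975), 12, 13, 10 and 1 for the genotype pairs and 0 for the difference at 0.5 (1163). Date 2 alone gave 2043 and 0 (3018) in WT, 23, 20, 121 and 1 for the pairs, and 922 and 0 (3504) for the differences. The sex score gave 0 in WT at 0.35 (1730) and 0 for the difference at 0.35 (2175). Vehicle arrays alone gave 22, 15, 4 and 4 for the pairs.

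Pairing arrays by replicate number, as a block, gave 72 in WT at 0.5 and 0 for the difference at 0.35 (3870 at an unadjusted p under 0.05). The numbers do not pair the samples, since 265 pairs with the same number in different groups had a mean correlation of 0.027 (-0.570 to 0.758).

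Without KO 0.35 replicate 5 there were 489 in WT at 0.5, 2314 for R192 against arrays labelled KO, 17 for R192 against Q192, and 2480 and 2075 for the differences. Without the 3 arrays of high Xist there were 0 (569) and 311 in WT and 0 (1894) and 0 (4458) for the differences. Without all 4 there were 0 (724) and 825 in WT, 131, 153, 2808 and 25 for the pairs and 0 (3282) for the difference at 0.35. The brainstem covariate gave 0 (291) and 587 in WT and 0 (346) and 2139 for the differences. The first-axis covariate gave 8 in WT at 0.5, 92, 150, 823 and 7 for the pairs, and 0 (620) for the difference at 0.5, where it reversed Ncdn (-0.087), Fasn (-0.033) and Mir99ahg (0.018). Of the 823 genes, 464 were among the 839.

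Leaving out each array in turn gave 1 to 1328 and 0 to 834 in WT, 46 to 77, 42 to 78, 365 to 2314 and 6 to 12 for the pairs, and 0 to 2480 and 0 to 2979 for the differences. Of 214 named results, 206 kept their direction and side of the threshold without the date covariate, 208 without the number correlation, 191 with the replicate number, 183 without the filter, 179 with centring, 197 with array weights, 195 with the sex score, 85 on date 1 and 91 on date 2. There were 214 without KO 0.35 replicate 5, 187 without the arrays of high Xist, 209 without all 4, 205 with the brainstem covariate, 151 with the first-axis covariate and 164 at the lowest values of leaving out each array. Of 213 results with every probe set tested, 212 did so, and of 110 with vehicle arrays alone, 28. Those that did not kept their direction, apart from the 3 reversals above. The preset list test called 4 to 21 of 31 lists over these settings, and the estimated correlation called 0 or 1. The number of arrays per group, 3 to 6, limits the precision.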

Other observations

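Genes of the daily clock and of glucocorticoid response lay lower in R192 than in arrays labelled KO. Of 18 circadian clock genes, 17 were lower (median -0.11), with 2 passing over all genes tested and 7 adjusted over the list alone (adjusted p = 4.67e-05, and adjusted p = 0.279 with an estimated correlation). Of 22 glucocorticoid-responsive genes, 19 were lower (median -0.12), with 3 passing over all genes and 7 adjusted over the list alone (adjusted p = 0.000417, and adjusted p = 0.379 with an estimated correlation). Sgk1, a kinase gene induced by glucocorticoids, had -0.41 (SE 0.108, adjusted p = 0.0176, lower in 13 of 14 arrays), Ciart, a repressor gene of the clock, -0.33 (SE 0.096, adjusted p = 0.0344, lower in 13 of 14, with -0.17 for its other probe set) and Per1, a core clock gene, -0.30 (SE 0.092, adjusted p = 0.045, lower in 12 of 14). Sgk1 missed the threshold without KO 0.5 replicate 1 (adjusted p = 0.054), Ciart (adjusted p = 0.0973) and Per1 (adjusted p = 0.109) without R192 vehicle replicate 2.

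Choroid plexus and meninges markers lay higher in R192 than in Q192. Of 19 choroid plexus and ependyma markers, 17 were higher (median +0.17), with 0 passing over all genes and 5 adjusted over the list alone (adjusted p = 2.22e-07, and adjusted p = 0.423 with an estimated correlation). Of 20 meninges and fibroblast markers, 20 were higher (median +0.11), with 0 passing over all genes and 0 adjusted over the list alone (adjusted p = 2.69e-05, and adjusted p = 0.532 with an estimated correlation). Of 30 brainstem and midbrain neuron markers, 24 were lower (median -0.031), with 0 passing over all genes and 0 adjusted over the list alone (adjusted p = 0.179, and adjusted p = 0.729 with an estimated correlation). Nnt, which is disrupted in the C57BL/6J substrain, was 8.84 ± 0.15 (SD, n = 12) in arrays labelled KO, 8.86 ± 0.22 (n = 15) in WT, 8.31 ± 0.21 (n = 14) in Q192 and 8.54 ± 0.33 (n = 14) in R192. Besides KO vehicle replicate 4, Xist was high in WT 0.35 replicates 1 (11.06) and 2 (11.33), the arrays with the lowest brainstem markers.

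The tests of this paragraph were chosen only after the result was seen. A hypothesis is that part of the genotype differences may come from chromosome segments that differ between the lines, in which genes that pass would lie beside each other. Of the 54 genes placed that passed between arrays labelled KO and WT, 26 had another among the 5 next tested genes on either side, where 10000 random draws gave a mean of 1.89 and at most 13. Of the 60 between Q192 and arrays labelled KO, 19 did, where the draws gave a mean of 2.33 and at most 14. Neighbours that are regulated together would give the same pattern, and the positions are those of the GRCm38.p6 gene table.

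Other splits of the same arrays were a planned test. Few splits gave as many genes for the genotype pairs, each count including the real split. For arrays labelled KO against WT 4 of 100 did (56, highest other 604). For Q192 against arrays labelled KO 2 of 100 did (60, highest other 189). For R192 it was 1 of 100 against arrays labelled KO (839, highest other 3) and 1 of 100 against Q192 (11, highest other 1). The splits moved arrays singly, so arrays sharing a description number could be parted, which the real groups rarely did. These shares alone therefore do not exclude chance. For the difference of the CPO effect between arrays labelled KO and WT at 0.5, 3 of 100 splits gave as many (1375, highest other 2600). Larger shares were found in WT at 0.35 (17 of 100, 1 gene, highest other 2496) and 0.5 (8 of 84, 155 genes, highest other 1332). The same held for the difference at 0.35 (25 of 100, 1 gene, highest other 4561). Chance was therefore not excluded in these either, nor in the difference at 0.5, where splits could part arrays as well. With 0 genes by limma in the real split, every split gave as many. This held for 100 of 100 splits in arrays labelled KO at 0.35 (highest other 4180) and 35 of 35 at 0.5 (highest other 1), and for 100 of 100 in Q192 (highest other 6 and 0), R192 (0 and 0), the mean of genotypes (2356 and 3995) and R192 minus Q192 (431 and 0). Some of these splits gave far more genes than the real one. Where the real count was 0, they gave up to 4180 in arrays labelled KO at 0.35, 2356 and 3995 on the mean of genotypes, and 431 for R192 minus Q192 at 0.35. They gave several times the real count in WT at both doses and for the difference between arrays labelled KO and WT at 0.35. The same held for arrays labelled KO against WT and for Q192 against arrays labelled KO. Such splits may reflect a structure of the arrays other than the groups compared, but what they have in common was not tested.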
